A study of Mus musculus with 8 samples.

How the data were processed

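Gene expression was measured on Affymetrix arrays in dermal fibroblasts sorted from the skin of 8 male C57Bl/6 mice, 4 young (2 months) and 4 old (18 months), with 1 array per mouse. Per the labels' protocols, skin without its subdermis was digested with collagenase, and cells lacking CD45, CD117, CD24, CD31 and EpCam but carrying Pdgfra and CD34 were collected by flow cytometry. RNA came from 5000 cells per mouse, was amplified for 21 cycles, and 8 µg of cDNA was labelled, per the labels' protocols. A pair of young and a pair of old mice was taken on each collection day, but which mice shared a day is not stated, so the day could not be a term of the fit. Each array comes from a separate animal, so the replicates are biological.

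The deposited values are log2 expression values per probe set. The authors made them with RMA and affy, per the submitters' processing notes, which give no versions or parameters. RMA adjusts background, normalizes arrays to a common distribution and summarises the probes of a set. The array version and any filter on probe sets are not given in the sources used here. The file held 45141 probe sets for 8 arrays with values rounded to 2 decimals, and no arrays were identical (0 duplicated). No detection calls were used here. The median of the 23 non-specific control probe sets was 3.90, with single values from 2.98 to 7.20. The median of all probe sets' means, 5.10, served as the threshold below which a probe set is called dim. A value above 5.10 can thus still lie within the range of these controls. The number of arrays limits the precision.

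Gene names came from the platform annotation given with the series, updated through gene identifiers in a table of mouse genes, in which 28689 probe sets matched and 0 symbols needed a change. Of the probe sets, 28898 had 1 gene symbol, 551 had several and 15692 had none in that annotation. Only those with 1 symbol were named. For the 7180 genes with several probe sets, the probe set with the highest mean over all 8 arrays was kept, which left 17097 genes. No genome build is named for the values, so no coordinates are given.

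Old mice were compared with young mice with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all 17097 genes and a threshold of adjusted p under 0.05. Every adjusted p of a gene given in the text comes from this limma fit, and changes are log2 values of old minus young with their standard error (SE). Sets of genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 38 lists with at least 5 measured genes. There were 24 gene lists and 15 lists of cell type markers, with 688 symbols, of which 601 were measured (3 through a synonym). The erythrocyte markers, with 3 measured, were not tested. The camera test with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance, were run as alternatives. The spread between mice was compared as the median over genes of the log2 ratio of SDs. A permutation test used all 35 splits of the 8 group-centred profiles, with a smallest possible p of 0.0286. Profiles centred within groups are not strictly exchangeable between groups, so its p is approximate.

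The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold whose groups did not overlap and whose brighter group lay above the dim threshold, the 12 largest changes in each direction. It also took up to 4 members with the smallest p from each list, and all genes of the sorting gate. Further list members past the threshold are named where a count is small, and these were chosen after their values were seen.

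The alternatives changed the prior of eBayes (by mean level, or robust), array weights, the filter on dim genes, the handling of several probe sets, the scaling of arrays, the threshold, the list test and the set of mice, leaving out each in turn. A further fit took the number in the sample titles as a block of 2 levels, each holding 2 young and 2 old mice. Each level has the makeup stated for a collection day, but whether the levels are the days is not stated. A fit on the dimmest probe set of each gene above the dim threshold was added after seeing the data. The scripts were tested on simulated arrays with the means and SDs of the 17097 genes, comparing old against young: of 50 genes changed by 0.5, 1, 2 and 3 (log2), 54%, 92%, 100% and 100% were recovered, and 2.26% of calls were false. With no gene changed, limma made 0 calls. In a simulation without correlation between genes, camera called the 1 list that had been shifted and no other. A true log2 SD ratio of 0.58 was estimated as 0.58. All of these simulations drew each gene independently and held no difference between the levels of title numbers. They cannot show how deviations shared across genes affect the limma calls or the SD ratio.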

Results

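The data cover 8 expression arrays of Pdgfra-positive, CD34-positive dermal fibroblasts, the collagen-producing cells of the dermis, from 4 young mice (2 months) and 4 old mice (18 months). The comparison asks how age alters the transcriptome of these cells. Array medians lay between 5.06 and 5.14 and array maxima between 13.22 and 13.32 on the log2 scale. The first principal component held 40.4% of the variance and parted young from old. The second, with 22.7%, parted the mice of both ages by the 2 runs of numbers in their titles. Old replicates 1 and 2 lay at -22.09 and -4.29 and old replicates 3 and 4 at 19.74 and 16.13, while young replicates 1 and 2 lay at -4.88 and -7.80 and young replicates 3 and 4 at 2.08 and 1.11. Across genes above the dim threshold, the difference between the runs in old mice had r = 0.303 with that in young mice (genes are not independent replicates). Deviations from the mean of each age correlated by 0.072 to 0.241 in the 8 pairs of a young and an old mouse within a run and by -0.256 to -0.022 in the 8 pairs across runs.

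**Figure D1:**
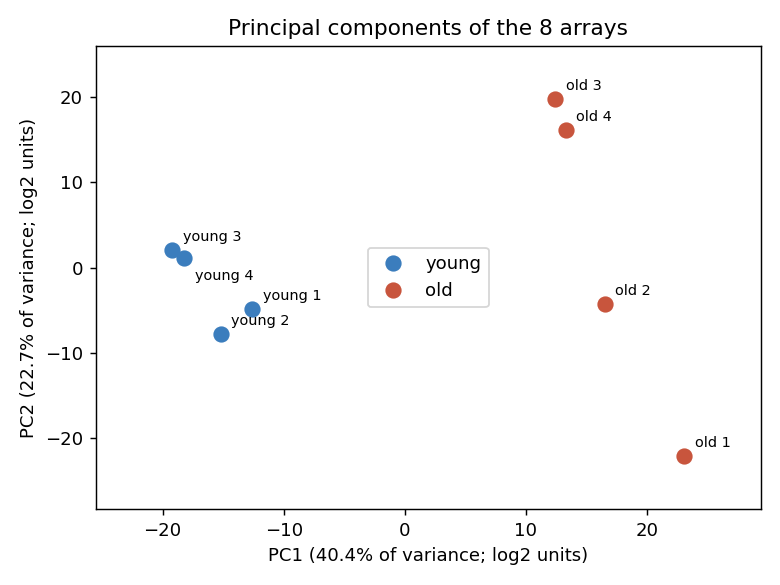
Principal components of the 17097 genes, 1 point per mouse, in log2 units with the share of variance on each axis. The 4 young mice lie at or below -12.60 and the 4 old mice at or above 12.43 on the first component, and old replicate 1 is lowest on the second (-22.09).

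Old fibroblasts carried more transcript of Pltp, Lgr5 and several complement genes and less of Coch, Fmod, Tnc and several collagen genes. Of 17097 genes, 679 passed limma's threshold, 311 higher and 368 lower in old mice. Changes of at least 2-fold numbered 71 higher and 88 lower. Groups did not overlap for 1658 genes, or 9.7% against the 2.86% that chance gives for 4 against 4, and 676 of the 679 genes were among them. Leaving out single mice lowered the count to 427 without old replicate 2, 445 without old replicate 4, 448 without young replicate 3 and 451 without old replicate 3. Across genes above the dim threshold, the changes within the 2 runs of title numbers had r = 0.626.

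By the brightest probe set of each gene, the largest increase was in Pltp, which encodes the phospholipid transfer protein: it rose from 8.28 ± 0.30 in young to 11.63 ± 0.08 in old mice (SD, n = 4 each), a 10.2-fold change (limma adjusted p = 8.11e-06). Lgr5, a receptor for R-spondins known as a stem cell marker, rose by 3.08 ± 0.33 (SE) and Ctla2a, a cysteine protease inhibitor, by 2.94 ± 0.21. Mlana, a protein of pigment granules, rose by 2.88 ± 0.34 from 6.22 ± 0.59 to 9.10 ± 0.61 (SD, n = 4). Increases from 2.26 to 2.75 followed in Nkain4, Plcxd3, the glycosyltransferase gene Galnt15, the carboxylesterase gene Ces1d, Clic5, Tmem176b, Prss23 and the interferon-inducible Ifi204. The other probe set of Ctla2a changed by 3.40, that of Lgr5 by 0.60 and that of Galnt15 by 0.51, and those of Clic5 and Prss23 by as little as 1.00 and 0.66. Prss23 lost its call without young replicate 1 (2.20, limma adjusted p = 0.105) and without 5 other mice in turn.

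The largest decrease was in F13a1, the A subunit of coagulation factor XIII, which fell by 2.96 ± 0.38 (SE), from 8.46 ± 0.85 to 5.50 ± 0.42 (SD, n = 4; limma adjusted p = 0.00288). Coch, a secreted matrix protein, fell by 2.80 ± 0.30, and Adam12, a metalloprotease, fell by 2.71 ± 0.36. The collagen-binding proteoglycan gene Fmod fell by 2.58 ± 0.19 and the matrix glycoprotein gene Tnc fell by 2.51 ± 0.41. Cd24a fell by 2.74 ± 0.27, and Fcgr3, a receptor for immunoglobulin G, fell by 2.39 ± 0.11. Moxd1, Crabp1 (a retinoic acid-binding protein), the ferric reductase gene Cybrd1, Aldh1a7 and Col11a1 had changes from -2.47 to -2.08, all past the threshold. The second probe sets of Tnc and Col11a1 changed by -0.20 and -0.11. That of Col11a1 had a mean of 3.57, below the non-specific control median of 3.90, where a change could be missed.

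**Figure D2:**
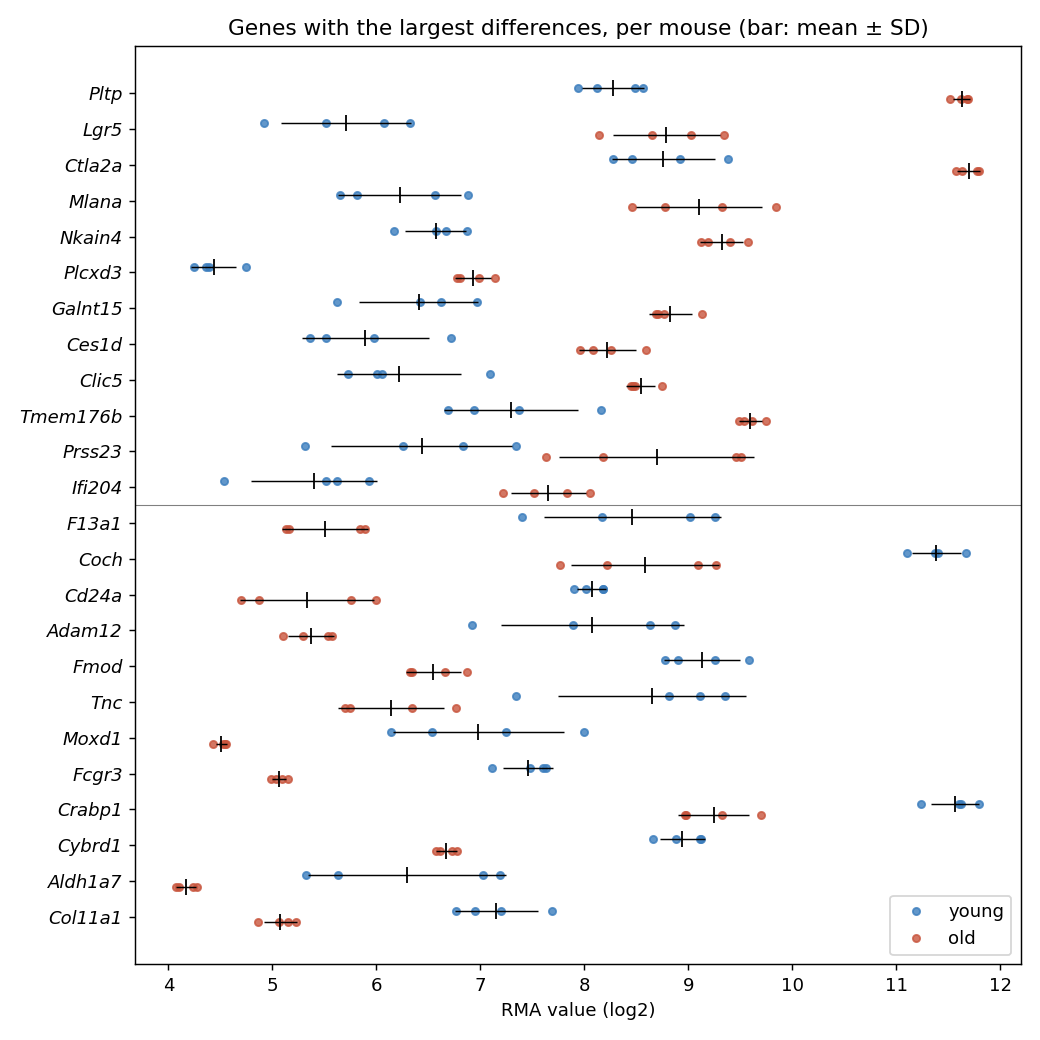
RMA values (log2) of the 12 genes with the largest increase and the 12 with the largest decrease in old mice, 1 point per mouse, with the mean and SD of each group of 4. Young and old values do not overlap for any of these 24 genes; Pltp lies at 11.63 on average in old and 8.28 in young mice.

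By list, 12 of 38 passed camera, 5 upward and 7 downward. With an estimated correlation 0 of 38 passed by limma's camera (6 at an unadjusted p under 0.05, lowest adjusted p = 0.131), and fry called 8. The other splits of the same mice gave a median of 5.5 lists and up to 11. Of these, the 16 that kept 3 mice of an age together hold part of the age difference, and the 18 with 2 mice of each age on both sides gave a median of 4 and at most 7.

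Several collagens were lower in old fibroblasts. Of the 18 collagen genes of the list, 6 fell, none rose and 12 did not pass; adjusted over the list alone, 10 fell. The median change of these 18 was -0.38 (camera adjusted p = 1.4e-11; adjusted p = 0.131 with an estimated correlation). Among all 42 measured collagen genes, a set chosen after the values were seen and not tested with camera, 8 fell and 2 rose, the latter being Col4a3 and Col4a4, and the median change was -0.10. Col11a1 fell by 2.08 ± 0.18, the basement membrane genes Col4a2 and Col4a1 by 0.67 ± 0.08 and 0.48 ± 0.07, and Col5a3 by 0.98 ± 0.11 (SE, n = 4 against 4), with Col15a1 and Col6a2 also lower; another probe set of Col4a1 fell by 0.73. Col1a1, the main collagen of the dermis, changed by -0.05 ± 0.06 at a level of 13.13 in young mice, close to the array maxima. The bright probe set of Col3a1 (mean 12.66) changed by -0.02 ± 0.07 and a dimmer probe set of the same gene (mean 10.14) by -0.77 ± 0.14.

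Several matrix glycoproteins and proteoglycans were lower in old fibroblasts. Of 32 measured, 8 fell and 3 rose; adjusted over the list alone, 9 fell and 5 rose (median -0.12, camera adjusted p = 0.0273; adjusted p = 0.552 with an estimated correlation). Postn, or periostin, fell by 1.59 ± 0.22 and Mfap4 by 0.66 ± 0.12, beside Fmod and Tnc. Those that rose were Efemp1, Nid1 and Tgfbi, with limma adjusted p = 0.0769 without old replicate 4, 0.11 without young replicate 1 and 0.105 without young replicate 1. None of these 3 passed without young replicates 1 or 4 or old replicates 2 or 4 in turn, and 1 of the 32 rose without young replicates 2 or 3 or old replicate 3. Without young replicate 1, young replicate 3 or old replicate 4, 5 of the 32 fell, and the median was -0.06 with the mean of probe sets. The list lost its camera call with dim genes left out (adjusted p = 0.0739) and without old replicate 1 (adjusted p = 0.059), young replicate 3 (0.072) or old replicate 4 (0.0722). Of 21 genes of collagen synthesis and crosslinking, 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.267, or 0.0477 without young replicate 4): the lysyl oxidase genes Loxl1 and Lox rose by 0.59 ± 0.09 and 0.35 ± 0.06 (other probe sets 1.27 and 0.20 to 0.46), while Loxl2, Loxl3 and Plod1 fell. These 3 lost their limma call in 1, 6 and 7 of the fits without 1 mouse, and none of the 3 passed without old replicate 4. Limma adjusted p was 0.0546 and 0.0816 without old replicate 4 for Loxl2 and Loxl3 and 0.132 without young replicate 2 for Plod1. Plod1 also lost its call with the title number block, the robust prior, the mean of probe sets and arrays centred on their median. Its dimmest probe set above the dim threshold changed by -0.055 (limma adjusted p = 0.916). Of 20 matrix proteases and inhibitors, 2 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.878, with a median of 0.06 and a mean of -0.04). The protease inhibitor gene Timp3 rose by 1.24 ± 0.13, and the protease genes Adamts9, Mmp19 and Mmp3 fell by 1.73 ± 0.20, 0.61 ± 0.09 and 0.46 ± 0.07; the probe sets of Adamts9 ranged up to 0.03 and its dimmest above the dim threshold did not pass (-0.33, limma adjusted p = 0.216). Adamts1 was the other that rose. It lost its limma call in 7 of the fits without 1 mouse (adjusted p = 0.119 without old replicate 4). Adamts1 also lost it with arrays centred on their median and on its dimmest probe set above the dim threshold.

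Complement genes were higher in old fibroblasts. Of 11 measured, 6 rose and none fell, and 6 rose adjusted over the list alone (median 0.42, or 0.83 with dim genes left out; camera adjusted p = 5.88e-07; adjusted p = 0.134 with an estimated correlation). C2 rose by 1.94 ± 0.12, C1s1 by 1.91 ± 0.22, Cfb by 1.75 ± 0.23 and C1ra by 1.35 ± 0.09 (SE, n = 4 against 4). All 4 encode proteases of the complement cascade. Serping1, another that rose, lost its call in 7 of the fits without 1 mouse. Its limma adjusted p was 0.103 without old replicate 2, where 5 of the 11 rose. Of 24 cytokine and chemokine genes, 5 rose and 1 fell (5 and 3 adjusted over the list alone), and the list did not pass (median 0.07, camera adjusted p = 0.151). That median was 0.02, 0.03 and 0.15 without young replicates 2, 3 and 4 in turn, 0.045 without old replicate 3 and 0.12 with array weights, and the list passed in none of these. The chemokine genes Cxcl12 and Ccl11 rose by 1.78 ± 0.26 and 1.41 ± 0.17, and Lif by 0.69 ± 0.12. Other probe sets of Cxcl12 and Lif changed by as little as 0.20 and -0.01, and Cxcl12 did not pass on the dimmest above the dim threshold (0.72, limma adjusted p = 0.0597). Icam1 and Il6 also rose and Vcam1 fell. Each lost its limma call in 6 of the fits without 1 mouse. Limma adjusted p reached 0.0825 for Icam1 (without old replicate 2), 0.114 for Il6 (without young replicate 3) and 0.103 for Vcam1 (without young replicate 1). Il6 also lost its call with arrays centred on their median. Without old replicate 1, old replicate 3, young replicate 2 or young replicate 3, 3 of the 24 rose. Of 22 interferon response genes, 2 fell and none rose (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.135); these were Oasl2 and Ifi27l2a, with limma adjusted p = 0.0556 without old replicate 4 and 0.0998 without old replicate 2, and neither passed without old replicates 1, 3 or 4 in turn. Iigp1 changed by 1.11 and passed limma's threshold in 6 other settings, such as the title number block (adjusted p = 0.0494). Of 11 class I antigen presentation genes, 0 passed limma's threshold (4 at an unadjusted p under 0.05; 3 rose adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0341; adjusted p = 0.619 with an estimated correlation). The median was 0.18 without young replicate 2, 0.16 without old replicate 3 and 0.054 with array weights. Psme1 passed with array weights and without old replicate 1. The list's call was absent with array weights (0.0564) and without old replicate 2 (0.117), young replicate 3 (0.108), old replicate 3 (0.0621) or young replicate 4 (0.0862).

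Adipogenic and lipid genes shifted upward by a small amount. Of 25 measured, 3 rose and none fell, and 7 rose adjusted over the list alone (median 0.07, camera adjusted p = 0.00919; adjusted p = 0.197 with an estimated correlation). The lipid carrier gene Apoe rose by 1.29 ± 0.19, the transcription factor gene Ebf1 by 0.85 ± 0.14 and the lipase gene Lpl by 0.65 ± 0.12 (SE). Lpl lost its limma call in 3 of the fits without 1 mouse (adjusted p = 0.055 without young replicate 3). It also lost it on its other probe set (0.27, limma adjusted p = 0.365). With the mean of probe sets 5 of the 25 rose. Pparg, the main transcription factor of adipocytes, changed by 0.20 ± 0.14 and the adipocyte genes Adipoq and Fabp4 by -0.02 ± 0.09 and -0.17 ± 0.18, and none of these passed. Mature adipocyte markers gave 0 of 8 past limma's threshold (1 at an unadjusted p under 0.05, camera adjusted p = 0.252). Of these 8, 5 lay below the dim threshold in both ages.

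**Figure D3:**
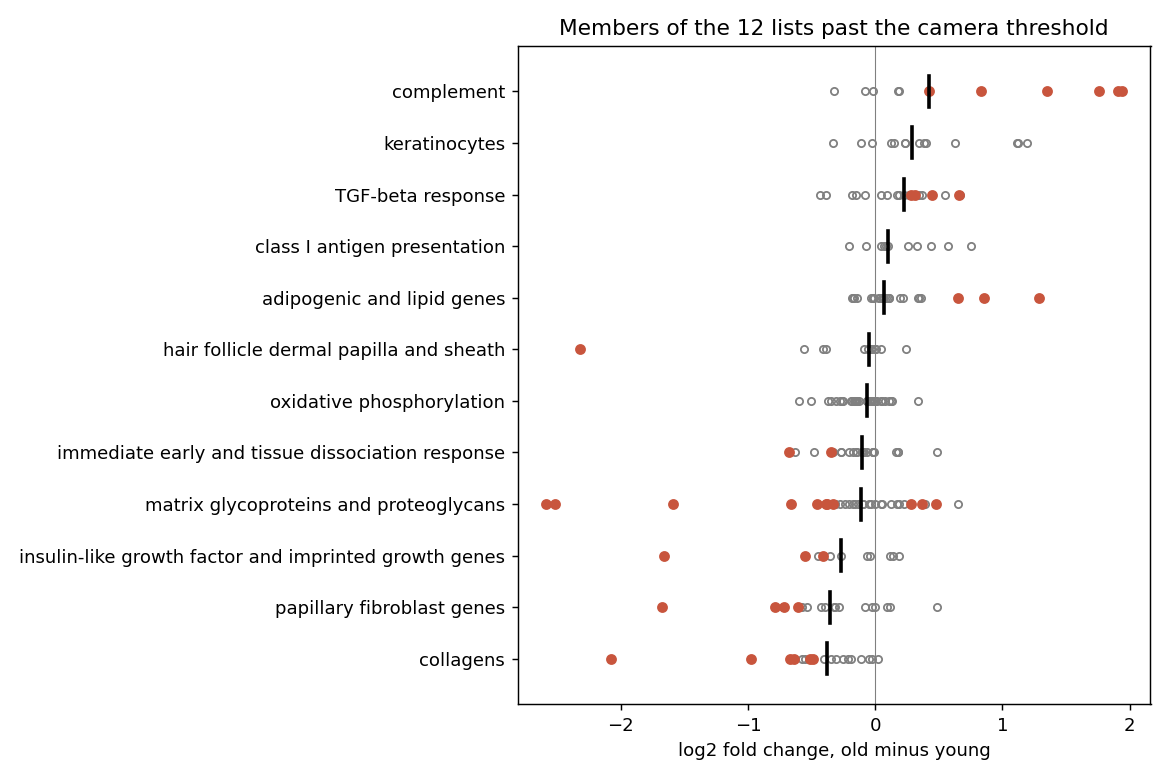
Log2 fold change (old minus young) of every measured member of the 12 lists that passed camera; filled points passed limma's threshold, open points did not, and the bar is the median. Collagens have the lowest median (-0.38) and complement the highest (0.42).

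Genes of senescence and its secretions moved both ways. Of 16 measured, 4 rose and 3 fell, with 6 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.146, or 0.0466 with the dimmest probe sets). Igfbp3 rose by 2.11 ± 0.31 and the cell cycle inhibitor genes Cdkn2b and Cdkn2a by 1.03 ± 0.15 and 0.82 ± 0.15, while Igfbp4 fell by 1.33 ± 0.19 and Mdm2 by 0.66 ± 0.06. Probe sets of Igfbp4 changed by as little as -0.55. Plau rose and Trp53inp1 fell, with limma adjusted p = 0.0728 without young replicate 3 and 0.072 without old replicate 3. They lost their calls in 6 and 5 of the fits without 1 mouse. Trp53inp1 also did not pass on its dimmest probe set above the dim threshold (-0.26, limma adjusted p = 0.436). Cdkn1a changed by 0.18 ± 0.07 and did not pass. Of 33 cell cycle genes, 0 passed limma's threshold (2 at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.551). The TGF-beta response list, which also holds receptor and Ltbp genes, shifted upward. Of 19 measured, 4 rose, with 8 higher and none lower adjusted over the list alone. At an unadjusted p under 0.05, 10 were higher and 3 lower. The median was 0.22 (camera adjusted p = 0.00162, or 0.131 with an estimated correlation). Among those that rose, the receptor gene Tgfbr2 changed most, by 0.66 ± 0.11 (its lowest probe set 0.02). The others were Ltbp4, Ltbp3 and Tgfbi, at limma adjusted p = 0.0546 and 0.0962 without old replicate 2 and 0.105 without young replicate 1. Ltbp4 and Ltbp3 lost their calls in 2 and 6 of the fits without 1 mouse, and Tgfbi in each of the 8. Of the 19 genes, 2 rose without old replicates 3 or 4 and 1 without old replicate 2 or young replicate 3. Of 24 Wnt signalling genes, 1 rose and 2 fell (1 and 7 adjusted over the list alone). The list had camera adjusted p = 0.0842, or 0.0375 without old replicate 2 and 0.0435 with a prior by mean level. The inhibitor genes Sfrp1 and Dkk2 changed by 1.04 ± 0.14 and -1.60 ± 0.23. Nkd2 fell, with limma adjusted p = 0.11 without young replicate 2 and 0.718 on its dimmest probe set above the dim threshold (-0.142). Nkd2 also lost its call with the mean of probe sets, with renewed quantile normalization and in 7 of the fits without 1 mouse.

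The list of insulin-like growth factor and imprinted growth genes shifted downward. Of 11 measured, 3 fell, none rose and 8 did not pass, and 4 fell adjusted over the list alone (median -0.27, camera adjusted p = 0.00343; adjusted p = 0.131 with an estimated correlation). Igf1 changed by -0.45 ± 0.17, Igf2 by -0.06 ± 0.18 and Igf1r by 0.12 ± 0.13, and none of these passed. Peg3 fell by 1.66 ± 0.18 and the noncoding RNA Meg3 by 0.56 ± 0.09 (SE). Plagl1 also fell and lost its limma call in 6 of the fits without 1 mouse (adjusted p = 0.0974 without old replicate 2).

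Genes of papillary fibroblasts, those of the upper dermis, were lower in old mice. Their list shares Apcdd1, Axin2, Lef1, Nkd1, Nkd2, Rspo1 and Wif1 with the Wnt list and also holds collagen genes such as Col7a1. Its result is therefore not independent of the Wnt result. Of 18 measured, 4 fell and none rose; adjusted over the list alone, 12 fell and 1 rose (median -0.36, camera adjusted p = 1.24e-05; adjusted p = 0.134 with an estimated correlation). Col7a1, the collagen of anchoring fibrils, fell by 1.68 ± 0.28 and Lrig1 by 0.79 ± 0.12. The others were Nkd2 and Prdm1 (limma adjusted p = 0.101 for Prdm1 without old replicate 4). Prdm1 lost its call in 6 of the fits without 1 mouse and with arrays centred on their median. Without young replicates 1 or 2 or old replicates 1, 3 or 4 in turn, 2 of the 18 genes fell, and 7 fell with array weights. In limma 1 gene rose with the title number block and in 4 other settings. Of 10 reticular fibroblast genes, 1 rose and 1 fell (2 and 2 adjusted over the list alone), Procr by 1.06 ± 0.07 and Fmo1 by -1.56 ± 0.21. The reticular median was also negative (-0.235, camera adjusted p = 0.494), though -0.058 without young replicate 1. Papillary and reticular lists were not tested against each other. Of 27 body position genes, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.878). The homeobox gene Meox2 fell by 1.96 ± 0.25, and Emx2 rose, with limma adjusted p = 0.129 without old replicate 2. Emx2 lost its limma call in 7 of the fits without 1 mouse. It also lost it with array weights, a prior by mean level or arrays centred on their median.

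Stress and metabolic lists moved little. Among 24 immediate early and dissociation response genes, 2 fell and none rose (2 and 1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0341; adjusted p = 0.568 with an estimated correlation). Klf2 fell by 0.68 ± 0.10, and Klf6 fell with limma adjusted p = 0.11 without old replicate 2. Klf6 lost its call in 7 of the fits without 1 mouse. It also lost it with arrays centred on their median and on its dimmest probe set above the dim threshold. Ccn1 changed by 0.48 and passed limma's threshold in 4 other settings, such as the title number block (adjusted p = 0.0359). The list lost its camera call with array weights (0.142), dim genes left out (0.114), the mean of probe sets (0.0785) or the dimmest probe sets (0.201), and without old replicate 1 (0.184), young replicate 2 (0.0599), young replicate 3 (0.0669) or young replicate 4 (0.113). Of 33 oxidative phosphorylation genes, 0 passed limma's threshold (5 at an unadjusted p under 0.05, 0 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0469; adjusted p = 0.742 with an estimated correlation). With the title number block 2 fell, Ndufa1 and Ndufa2 (limma adjusted p = 0.0197 and 0.0271), and 1 gene passed with array weights, a prior by mean level or renewed quantile normalization. The median was 0.04 without old replicate 1 (0.932) and 0.003 with array weights (0.742), but -0.105, -0.103, -0.15 and -0.16 without young replicates 1 and 2 and old replicates 3 and 4, and the call was also absent with dim genes left out (0.14) or arrays centred on their median (0.0734) and without old replicate 2 (0.118), young replicate 3 (0.196) or young replicate 4 (0.0685). Of 20 antioxidant genes, Txnrd1 and Gstm1 rose by 0.66 ± 0.09 and 0.58 ± 0.10 and Sod3 fell by 0.68 ± 0.09 (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0913, or 0.0144 without young replicate 3, 0.041 with dim genes left out and 0.0466 with the dimmest probe sets). Gstm1 and Sod3 did not pass on their dimmest probe set above the dim threshold (0.35 and -0.45, limma adjusted p = 0.146 and 0.304). Of 23 unfolded protein response genes, Asns fell by 1.01 ± 0.14, also over the list alone, and none rose (camera adjusted p = 0.362, or 0.0467 without old replicate 1). By limma, 0 of 16 circadian clock, 0 of 14 glycolysis and 0 of 26 ribosomal protein genes passed (7, 2 and 1 at an unadjusted p under 0.05; 3 clock genes, 2 higher and 1 lower, adjusted over the list alone), with camera adjusted p = 0.161, 0.164 and 0.363; the clock list had 0.0154 with the dimmest probe sets. With the title number block 2 clock genes rose, Bhlhe40 and Bhlhe41, and Clock fell (limma adjusted p = 0.0425, 0.0412 and 0.0436). Bhlhe40 also passed in 4 other settings and Clock without young replicate 2.

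Among the genes of the sorting gate, Cd24a, whose protein the gate excluded, was 8.07 ± 0.14 in young and 5.33 ± 0.64 in old mice (SD, n = 4; limma adjusted p = 0.000785). Adjusted over the list alone, 2 of these 7 genes were lower and 2 higher. Cd34 changed by 0.20 ± 0.06, Pdgfra by -0.59 ± 0.16 on a dim probe set (means 5.06 and 4.47), and Epcam by 0.40 ± 0.10, none past the threshold (limma adjusted p = 0.0808 for Pdgfra). Pdgfra passed with the title number block (adjusted p = 0.0464), with a prior by mean level (0.039) and without old replicate 3 (-0.71, adjusted p = 0.0352), and its adjusted p reached 0.187 without old replicate 4. Epcam passed with a prior by mean level (0.0441), array weights (0.0176) and without old replicate 1 (0.0242). The excluded Ptprc, Kit and Pecam1 changed by 0.08, 0.04 and 0.17. Ptprc (means 3.43 in young and 3.51 in old) and Kit (3.79 and 3.82) lay below the non-specific control median of 3.90, where a change could be missed. The list's median (0.08) and mean (-0.35) differed in sign (camera adjusted p = 0.878).

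Few markers of other cell types passed the threshold, but many lay below the dim threshold in both ages, where a change could be missed. This held for 9 of 16 macrophage and monocyte, 5 of 7 mast cell, 4 of 7 T cell and 6 of 12 skeletal muscle markers. It also held for 5 of 12 hair follicle markers and for 3 of 5 B and plasma cell, Schwann cell and sebocyte markers each. Fewer were dim among keratinocyte (3 of 14), endothelial (4 of 11) and mural (3 of 9) markers. Keratinocyte markers gave 0 of 14 past limma's threshold (2 at an unadjusted p under 0.05; 1 rose adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0341; adjusted p = 0.636 with an estimated correlation). Old replicate 3 carried the highest values of Krt10 (9.13), Dsp (7.76) and Perp (7.40), and without it the median was 0.14 and the camera adjusted p 0.221; it was also above 0.05 with dim genes left out (0.101) and without young replicate 1 (0.0579), young replicate 2 (0.0868) or young replicate 3 (0.1). Of the 14, Epcam passed limma's threshold with array weights, with a prior by mean level and without old replicate 1. Markers of hair follicle dermal papilla and sheath had a median of -0.04 over 12 genes (camera adjusted p = 0.0421; adjusted p = 0.378 with an estimated correlation), with Crabp1 the only one to pass limma's threshold and 3 lower adjusted over the list alone. The median was -0.02 without young replicate 1, -0.08 without young replicate 3, -0.10 without old replicate 1 and -0.39 with dim genes left out. That list call was absent in 6 of the fits without 1 mouse, up to adjusted p = 0.102 without old replicate 4, and with the mean of probe sets (0.0535). Of 6 melanocyte markers, Mlana alone rose (camera adjusted p = 0.0913; fry adjusted p = 0.0312). Of 7 T cell markers, Thy1, which fibroblasts also express, fell by 0.61 ± 0.07 (camera adjusted p = 0.439, median 0.01 and mean -0.07).

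Macrophage and monocyte markers gave 0 of 16 past limma's threshold (1 at an unadjusted p under 0.05; camera adjusted p = 0.0913), beside the falls in F13a1 and Fcgr3. By limma, 0 of 5 B and plasma cell, 0 of 7 mast cell, 0 of 11 endothelial, 0 of 9 mural and 0 of 5 Schwann cell markers passed (1, 0, 1, 1 and 0 at an unadjusted p under 0.05), with camera adjusted p = 0.231, 0.437, 0.914, 0.878 and 0.648. The B cell gene Cd79a passed in 5 other settings (lowest limma adjusted p = 0.0345, quantile normalized again) and the mural gene Myl9 without young replicate 4 (0.0387). The endothelial median (-0.00) and mean (0.02) differed in sign. Sebocyte and skeletal muscle markers, 0 of 5 and 0 of 12 by limma (0 and 1 at an unadjusted p under 0.05), both had camera adjusted p = 0.0913, and skeletal muscle passed without old replicate 3 (0.0292) and sebocytes without old replicate 4 (0.0343). The 3 erythrocyte markers had a median of 0.06 and a mean of -0.01, with 0 past the threshold in limma and 0 at an unadjusted p under 0.05.

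Old mice did not differ detectably from one another more than young mice did. Profiles were centred on age alone, so a difference between the runs of title numbers counts as spread here. Spread within runs was not tested. The median log2 ratio of SDs, old over young, was 0.14 (permutation p = 0.714, 2-sided, 35 splits). Median SDs were 0.13 in old and 0.117 in young mice (n = 4 each). Without old replicate 1 the ratio was -0.26 (permutation p = 0.257), and without young replicate 4 it was 0.38 (0.286). It was 0.064 without old replicate 3 and 0.21 and 0.24 without young replicates 1 or 3.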

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

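The tests of keratinocyte RNA and melanocyte RNA were chosen after the result was seen. A single mouse stood apart from the other 3 of its group in 11 of 246 groups of 4 values, where chance gives about 1 in 20. Among genes these were Clic5 in old replicate 4 (8.75, others 8.45 to 8.49), Col15a1 in old replicate 1 (11.1, others 11.2), Postn in young replicate 3 (9.91, others 9.31 to 9.37) and Tgfbr2 in young replicate 4 (9.97, others 10.4). The list values that follow are means over members of the difference from each gene's mean over 8 mice. Old replicate 1 was lowest of the old mice for matrix proteases and inhibitors (-0.0658), complement (0.284), interferon response (-0.231) and senescence genes (-0.0505). Young replicate 1 was highest of the young mice for complement (-0.139) and for mural cell markers (0.2), and old replicate 4 lowest of the old mice for macrophage markers (0.0187).

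The gene count was set against 35 splits of the 8 mice into 4 and 4. Only 1, the real one, gave as many as 679 genes. The highest of the others gave 0 genes by limma. At an unadjusted p under 0.05 in limma, the real split gave 2579 genes and the highest of the others 2270. Were the mice exchangeable, chance would be an unlikely account of the count of 679. For the lists at the preset correlation, 1 of the 35 splits gave as many as 12, the real one. The highest other gave 11, with 3 mice of an age against 1, and the 18 splits with 2 of each age on both sides gave at most 7. The real split thus led by a margin of 1 list and only at the preset correlation. With an estimated correlation 0 lists passed by limma's camera (6 at an unadjusted p under 0.05). As splits balanced for age also called lists, the count of 12 does not exclude chance for single lists. The mice also differed by their run of title numbers, so they are not plainly exchangeable and chance is not excluded for either count. The 18 splits with 2 mice of each run on both sides are too few for a share under 0.05 (smallest 0.0556). Among those, the real split gave 679 genes and 12 lists and the highest of the others 0 genes by limma (1021 at an unadjusted p under 0.05) and 10 lists. The split by title numbers itself gave 0 genes and 7 lists.

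Keratinocyte genes were high in old replicate 3. In the normalized values this array held the highest value for 11.5% of genes above the dim threshold. RMA brings arrays to a common distribution, so this share was largely set in advance. It cannot tell whether the array read high throughout before normalization. Keratinocyte RNA may have contributed: 7 of the 14 measured markers were highest there, under the 8 set as the bound for it and above the 4 set against it, so this stays open. Krt10 and Krt5, abundant in keratinocytes, reached 9.13 and 8.78, but Krt5 also lay at 8.43 in old replicate 4. Krt1 reached 6.38, against 4.28 to 4.98 in the other mice. Dsp and Perp reached 7.76 and 7.40, against at most 5.49 and 5.11 in the other mice. Krt14 reached 7, below young replicate 4 (7.29). Trp63 was highest in young replicate 1 (8.29), and Krt79 was lowest in old replicate 3 (4.8). The sort excluded EpCam-positive cells. No biological explanation was tested, since the mouse shares its group with 3 others.

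Mlana was 2.88 higher in old mice. RNA from melanocytes would bring the other pigment genes with it, and the other 5 measured melanocyte markers had a median change of 0.11. Dct changed by 0.10 and Mitf by 0.57, neither past limma's threshold (Mitf passed with array weights, adjusted p = 0.042). These values argue against melanocytes as the source. Of the markers, 3 (Dct, Tyrp1 and Tyr) lay below the dim threshold in both ages, and whether their probe sets detect melanocyte RNA was not tested. Mitf, like Mlana, was highest in old replicate 3 (8.74). Binding of another transcript to the 1 probe set of Mlana was not tested, and age itself remains open as a biological difference.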

How the results depend on the processing

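The fit on the dimmest probe sets was chosen after the data were seen; all other alternatives were planned. No direction of a called test reversed, though the oxidative phosphorylation median (-0.07) was 0.003 with array weights and 0.04 without old replicate 1. The 679 genes became 1082 (494 higher, 588 lower) at adjusted p under 0.1 and 396 (181 higher, 215 lower) with at least 1.5-fold, which follow from the thresholds. With array weights 473 rather than 311 genes were higher (old replicate 1 weighed 0.364), and the cause was not tested. Without 1 mouse in turn, genes changed ranged from 427 to 606, genes higher from 183 to 303, genes lower from 231 to 343 and lists from 7 to 11, with fewer samples in each fit; the count of 7 lists came without young replicate 3. With an estimated correlation, 0 of the 12 lists passed (6 at an unadjusted p under 0.05 in limma's camera): the collagen median stayed -0.38 with adjusted p = 0.131 and the adipogenic median 0.072 with 0.197, as each list was then charged with its own correlation. Over its other alternatives the collagen list kept its call, with adjusted p from 5.69e-15 to 0.00315. The block by title numbers gave 919 genes, of which 676 were among the 679, and 8 genes passed for the block itself. No paired analysis was possible because replicate numbers only name the mice. The dimmest probe sets gave 605 genes and a collagen median of -0.53. Of 108 called genes named in the text or run with it, 74 kept their call in every setting, 29 lost it without at least 1 mouse and 5 under another setting only: Adamts9, Cxcl12, Gstm1, Rian and Sod3, all with the dimmest probe sets. Of 93 genes run that did not pass, 21 passed in at least 1 other setting and 9 of them with the block by title numbers. The spread ratio ranged from -0.26 to 0.38 without 1 mouse and did not pass in any setting. Genes and second probe sets near the non-specific control median of 3.90 can hide changes, as can those near the array maxima. Levels of second probe sets are mostly not given here.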

Other observations

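The gene groups of this part were chosen after their values were seen, while the slope test was fixed before its result. Type IV collagens, which form basement membranes, moved apart: by limma Col4a3 and Col4a4 rose by 1.13 ± 0.17 and 0.94 ± 0.07 (SE), while Col4a1, Col4a2 and Col4a5 fell by 0.48 ± 0.07, 0.67 ± 0.08 and 1.12 ± 0.09. The second probe sets of Col4a3, Col4a4 and Col4a5 changed by 0.22, 0.34 and -0.16. The noncoding RNAs Meg3, Rian and Mirg, which share an imprinted locus, fell by 0.56 ± 0.09, 1.19 ± 0.13 and 0.56 ± 0.07; Rian lost its call on its dimmest probe set (-0.89, limma adjusted p = 0.0549). Spry1 and Spry4, inhibitors of growth factor signalling, fell by 1.33 ± 0.14 and 1.32 ± 0.24, as did Fgf2 by 1.04 ± 0.16, and a probe set of Spry4 changed by -0.16, whereas Spry2 changed by 0.03 ± 0.14.

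Of 13 replication-dependent histone genes, 5 fell and none rose by limma. H2bc22 fell by 1.82 ± 0.24, H4c8 fell by 1.72 ± 0.28 and H3c1 fell by 1.26 ± 0.17. H2bc4 and H3c14 also fell, with limma adjusted p = 0.0861 without young replicate 1 and 0.0994 without old replicate 4. Both lost their calls in 6 of the fits without 1 mouse. The second probe sets of H2bc22, H3c1 and H3c14 changed by -0.90, 0.12 and -0.12. Of 33 cell cycle genes, 0 passed limma's threshold and 2 had an unadjusted p under 0.05. Among probe sets without a gene name, 285 passed limma's threshold when all 45141 were tested singly, 141 higher and 144 lower in old mice.

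Of the 3 listed collagens with a probe set above 12 and another one, Col3a1 (-0.02 against -0.77) and Col5a2 (-0.11 against -0.61) changed less on the bright probe set, while Col5a1 did not differ so (-0.19 against -0.24 and -0.16). A signal ceiling of the array may account for the difference in Col3a1 and Col5a2. The test took only non-collagen genes with another probe set that lay above the dim threshold, was dimmer by at least 1 and changed at an unadjusted p under 0.05 in limma. Over the 14 of these whose brightest probe set lay above 12, the slope of its change on that of the dimmer one was 0.239 (95% bootstrap interval 0.126 to 0.405), against 0.763 (0.67 to 0.825) over the 179 of these from 9 to 11; genes without such a dimmer probe set are not covered. The change of Col3a1 may therefore be understated here. Col1a1 has 1 probe set and is not covered by the slope test, so whether its change is understated was not tested. Differences between the transcripts that the probe sets bind were not tested either.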
